A study of Ovis aries with 12 samples.

How the data were processed

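Gene expression was measured in 12 sheep placentomes, the units of the ruminant placenta in which fetal cotyledon and maternal caruncle interlock. Per the labels, 7 came from control ewes and 5 from ewes that received cortisol by continuous infusion at 1 mg per kg per day from about day 115 of gestation. Per the labels' protocols, total RNA was labelled with Cy3 and hybridised to 1-colour Agilent ovine arrays, 1 array per placentome. The titles give a gestational age of 140 days, and the series' design text gives early labor at 143 ± 1 days over a range of 139 to 144 days. The text does not choose between these ages. The labels' protocol text gives other numbers of infused ewes than the 7 and 5 arrays, and the groups used here follow the title of each sample. Each array is taken as a separate animal, though no label says so in words, so p-values measure the spread between these samples. Fetal sex was not given in the sources used here.

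The deposited array files hold spot intensities on a linear scale. Per the file headers, they were made with Agilent Feature Extraction 10.1.1.1 under the protocol GE1-v5_10_Apr08, and the processed signal used here is background-subtracted by that program. The deposited value table of the whole series holds log2 values with no scale, centring or direction stated. Each of its 12 columns followed its own array best, with r from 0.971 to 0.987 against the log2 processed signal, and the quartiles of its columns were nearly identical, which is what quantile normalization gives. The column medians were 6.56 in control 7, 6.54 in cortisol 1 and 6.55 in each of the other 10, with no centring of genes, and high values meant high signal. The lowest value of each column was negative, from -1.22 to -0.12, which on a log2 scale is a signal below 1 unit. The negative controls had mean signals of 38.2 to 92.6 units. If the table kept the units of the arrays, these values argue that background was subtracted, by a method that stays unknown. An array held 15744 spots, of which 15208 were not controls and covered 15008 probes of 60 bases. No spot was saturated on any array.

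Log2 of the processed signal was taken and each array's 75th percentile over the non-control spots was subtracted, so a value of 0 means the signal of that percentile. Spots of the same probe were averaged on the log2 scale, and control spots and spots marked as outliers by Feature Extraction were left out. A probe was tested if it was well above background on at least 5 arrays, the size of the smaller group, which kept 11515 probes. Of these, 26 had a missing value on some array because of a marked spot. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the default prior, group as the only term), two-sided, with Benjamini-Hochberg adjustment over all probes tested and a threshold of 0.05. Fold changes are cortisol over control. Where a probe was not well above background on any array of a group, its measured fold is not given, and a fitted value appears only where it changed sign under an alternative. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.28.

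Gene names came from the array files, updated through a RefSeq gene table (assembly ARS-UI_Ramb_v3.0, used for names only). Of the 15008 probes, 698 were named through an accession, 497 by a current symbol, 125 through a gene identifier, 20 through a synonym and 128 through a table of older names. A further 118 kept the file's name, and 8 kept the file's symbol where the accession pointed elsewhere. Together 1594 probes had a symbol, for 964 genes. The other 13414 probes carried only a sequence accession or a locus number and are unnamed here, so gene-level statements cover a small part of the array.

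The designs, the alternatives, the rule for named genes and 30 gene lists were fixed before the data were examined. The rule names, in each direction, the 10 genes with the largest log2 fold change past the adjusted threshold and with the same sign within both slides. Where fewer pass, it fills to 10 by the smallest unadjusted p among probes with the same sign within both slides. It also names up to 4 members of each list by smallest unadjusted p, and corticosteroid receptors and enzymes, PTGS2 and standard cortisol-responsive genes where measured. In lists a gene counts once, through its tested probe with the highest mean signal. No probe passed the adjusted threshold, so all 20 genes of the first part were filled in by unadjusted p. Naming 2 members of each list rather than 4 was settled after the values were seen, and so was treating the median of a list as a value with no test of its own. A few further list members are given as examples of their list. FKBP5, TSC22D3 and PER1 were not found on the array by name. Lists with at least 5 measured members were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and fry beside it, adjusted over the 26 lists tested. Members with a missing value, 8 in all, were left out of the set tests.

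Array headers placed the arrays on 2 slides, each scanned in its own run. Slide 1 held 4 control and 4 cortisol arrays and slide 2 held 3 control arrays and 1 cortisol array. Values are given with slide as a block and within each slide for the lists and the 20 genes of the first part, and for other named genes the value with slide as a block is given where it moved by over 1.5 times, and the value within a slide where its direction turned. In the fit within slide 2 the lone cortisol array is assumed to vary like the controls. The titles number the replicates from 1 in each group and nothing in the labels ties equal numbers together. The highest correlation between any pair of arrays was 0.985 over 11489 probes, so no array was a copy of another.

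The fit and the set test were tested on simulated data with the means and spreads of the 11515 tested probes, in which 200 probes were changed. At a log2 change of 1, 34 of 100 changed probes were called, and at a log2 change of 2, 72 of 100. Of 11298 unchanged probes 5 were called. A list of 17 members shifted by 1 was called and none of the other lists was. The simulated probes varied independently of each other, whereas the trophoblast list had an estimated correlation of 0.294 in the data. The simulation therefore does not show how the set test behaves with correlated members.

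Alternatives were normexp background correction (offset 50), quantile normalization, median centring, the authors' value table, no filter on dim probes, a filter on all 12 arrays, slide as a fixed or random block, each slide alone, the replicate number as a block, a trended and robust prior, array weights, averaging the probes of a symbol, keeping marked spots, and leaving out each array. Leaving out cortisol 2 and cortisol 5 together, fitting replicates 1 to 5 without a block, and normexp followed by quantile normalization were chosen after seeing the data.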

Results

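Placentomes of control ewes (7 arrays) and of ewes infused with cortisol (5 arrays) were compared on 12 arrays of 15008 probes. The 75th percentile of the signal ranged from 251 in cortisol 4 to 791 in cortisol 5, and 67.5% to 85.7% of the spots were well above background. The arrays of cortisol 2 and cortisol 5 stood apart from the other 10. In cortisol 2 the negative controls had a mean signal of 92.6, against 38.2 to 43.1 on the other arrays, and its median correlation with the other arrays was 0.847. Cortisol 5 had the widest signal range, with a log2 distance of 3.01 between the 75th percentile and the median, and was the lone cortisol array on slide 2.

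**Figure D1:**
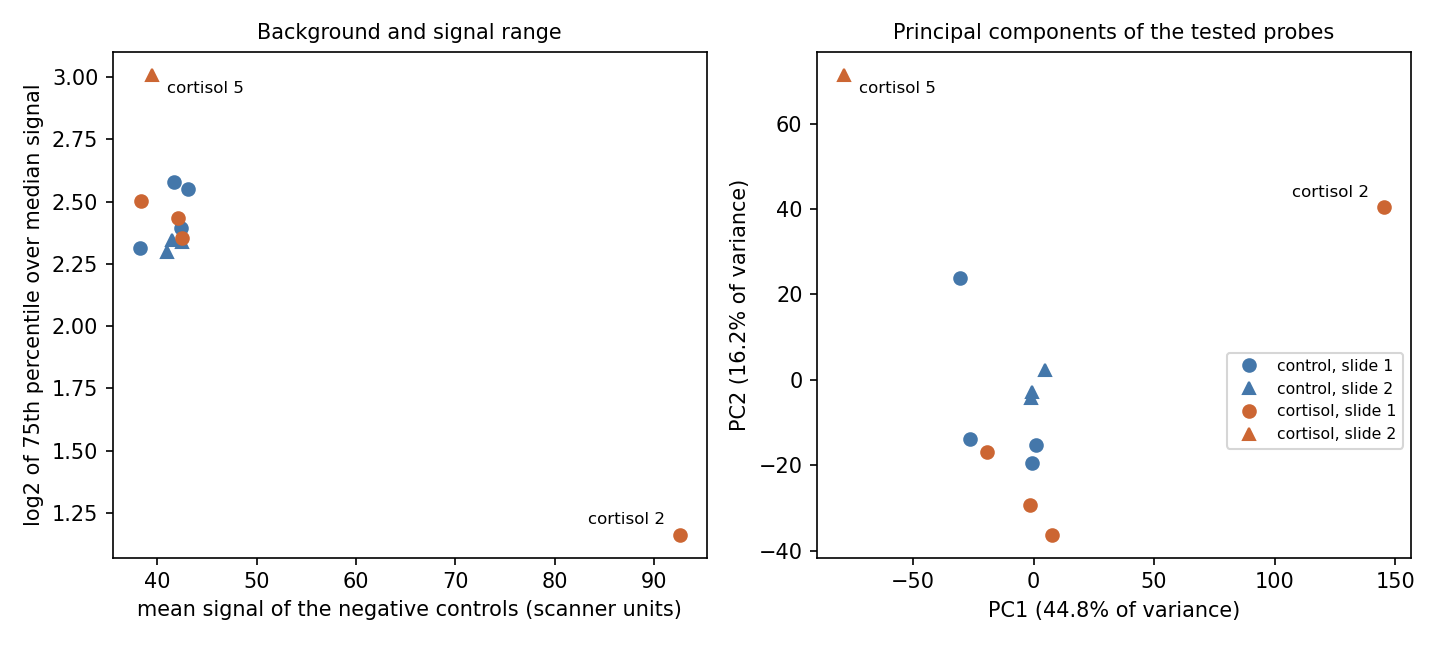
The left panel plots, for each of the 12 arrays, the mean signal of the negative controls in scanner units against the log2 ratio of the 75th percentile to the median signal, and the right panel plots the first and second principal components of the tested probes, with colour for the group and shape for the slide. Cortisol 2 sits at a negative control mean of 92.6 and a log2 ratio of 1.16, and cortisol 5 at a log2 ratio of 3.01.

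The comparison of cortisol with control addresses how a raised maternal cortisol level in late gestation relates to gene expression in the placentome. The named genes with the smallest unadjusted p included CTSD, a lysosomal protease, BMP7, a secreted growth factor, and PGF, a growth factor of the VEGF family that acts on blood vessels. CTSD had a log2 mean of 3.07 ± 0.40 (SD, n = 5) with cortisol and 4.19 ± 0.35 (SD, n = 7) in controls, a fold of 0.459. PGF was at 0.356-fold and BMP7 at 0.447-fold of control. CTSD, PGF and BMP7 were each below the control mean on 5 of 5 cortisol arrays. The rule that named them favours such a count, since it asks for the same sign within both slides. ITLN2, a secreted lectin, was at 5.90-fold of control, with log2 means of -1.90 ± 1.05 (SD, n = 5) and -4.46 ± 1.58 (SD, n = 7), though it was well above background on only 6 of 7 control arrays. None of these differences passed the adjusted threshold.

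With limma, 0 of 11515 probes passed an adjusted p of 0.05, and 0 passed 0.10. The smallest adjusted p was 0.333. At an unadjusted p of 0.05, 618 probes passed, 118 higher and 500 lower with cortisol, where chance alone gives 576. With normexp the split was 158 higher and 316 lower. A trended and robust prior gave 0 probes after adjustment and 577 before it. With slide as a block, 0 probes passed after adjustment and 581 before it, 109 higher and 472 lower. Within slide 1 the balance of directions turned, with 0 after adjustment and 482 before it, 295 higher and 187 lower. Within slide 2, where the lone array of cortisol 5 is assumed to vary like the controls, 3564 probes passed after adjustment and 5393 before it. Without cortisol 5 the balance also turned, to 685 higher and 511 lower of 1196, and without cortisol 2 it was 213 higher and 985 lower of 1198. Without control 6, 72 of 448 were higher, and without cortisol 4, 1 probe passed after adjustment. The simulation recovered 34 of 100 probes with a log2 change of 1, so differences of this size were often not detectable with these arrays.

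Of the 10 genes named for lower values, PGF had a log2 fold change of -1.49 ± 0.41 (SE; limma adjusted p = 0.522), with -1.53 within slide 1 and -1.48 within slide 2. BMP7 had -1.16 ± 0.24 (limma adjusted p = 0.333), with -0.90 and -1.96 within the slides, and CTSD had -1.12 ± 0.23 (limma adjusted p = 0.333), with -0.98 and -1.52. A second probe gave -1.48 for PGF, -1.13 for BMP7 and -1.10 for CTSD. With slide as a block the values were -1.52 for PGF, -1.19 for BMP7 and -1.12 for CTSD. The other lower genes were CSNK1E, a kinase of the circadian clock, at -1.07, ARF1, a GTPase of the Golgi, at -0.97, and TIE1, a receptor kinase of endothelial cells, at -0.94. BAT3, a chaperone now named BAG6, and SLC39A3, a zinc transporter, were both at -0.83. SLCO2A1, a prostaglandin transporter, was at -0.71 and CD81, a tetraspanin, at -0.57. Their adjusted p ranged from 0.333 to 0.628, and each of the 10 was below the control mean on 5 of 5 cortisol arrays. The rule required the same sign within both slides, so agreement in sign between slides was set by the choice of genes. This choice also favours a count of 5 of 5, since cortisol 5 is alone on slide 2. With normexp, TIE1 was at -0.17, SLC39A3 at -0.46 and CSNK1E at -0.66. With slide as a block these 7 genes ranged from -1.02 for CSNK1E to -0.58 for CD81. Within slide 1 they lay between -0.83 for CSNK1E and -0.53 for TIE1, and within slide 2 between -2.09 for TIE1 and -0.43 for CD81. CTSD had its lowest control value in control 2, at 3.46 against 4.07 to 4.52 in the other controls.

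Of the 10 genes named for higher values, ITLN2 had a log2 fold change of 2.56 ± 0.73 (SE; limma adjusted p = 0.562), with 3.07 within slide 1, 1.68 within slide 2 and 2.69 with slide as a block. Its second probe gave 1.89 ± 0.87, and with normexp the first was at 1.19. PSPH, the last enzyme of serine synthesis, had 1.00 ± 0.40, CA11, a protein related to carbonic anhydrases, 0.83 ± 0.36, and PRP2, a prolactin-related protein of the trophoblast, 0.82 ± 0.34. CPT1B, which admits fatty acids to mitochondria, had 0.76 ± 0.28, with a value of -0.50 in cortisol 2, against -2.16 to -1.89 in the other cortisol arrays. PSPH was at -0.0031 in cortisol 2, against -2.82 to -1.59, and CA11 at -0.64, against -3.02 to -1.99. Without cortisol 2 the log2 fold changes were 0.56 for PSPH, 0.47 for CA11 and 0.45 for CPT1B. BCAT2, which starts the breakdown of branched-chain amino acids, had 0.59 ± 0.24 and TXNDC17, a thioredoxin-like protein, 0.57 ± 0.21. EDNRB, an endothelin receptor, had 0.53 ± 0.22 and turned to -0.0090 with quantile normalization. MGLUR4, a glutamate receptor, had 0.43 ± 0.18 and ENDOG, a mitochondrial nuclease, 0.33 ± 0.14. Their adjusted p ranged from 0.562 to 0.872. The 9 genes after ITLN2 ranged from 0.34 for ENDOG to 1.08 for PSPH with slide as a block. Within slide 1 they lay between 0.27 for ENDOG and 1.14 for PSPH, and within slide 2 between 0.33 for CPT1B and 1.32 for TXNDC17. PSPH, CA11 and PRP2 were above the control mean on 4 of 5 cortisol arrays and the other 7 genes on 5 of 5. The same rule on signs favours such counts here. The brighter probe of PRP2 gave 0.66 ± 0.38.

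**Figure D2:**
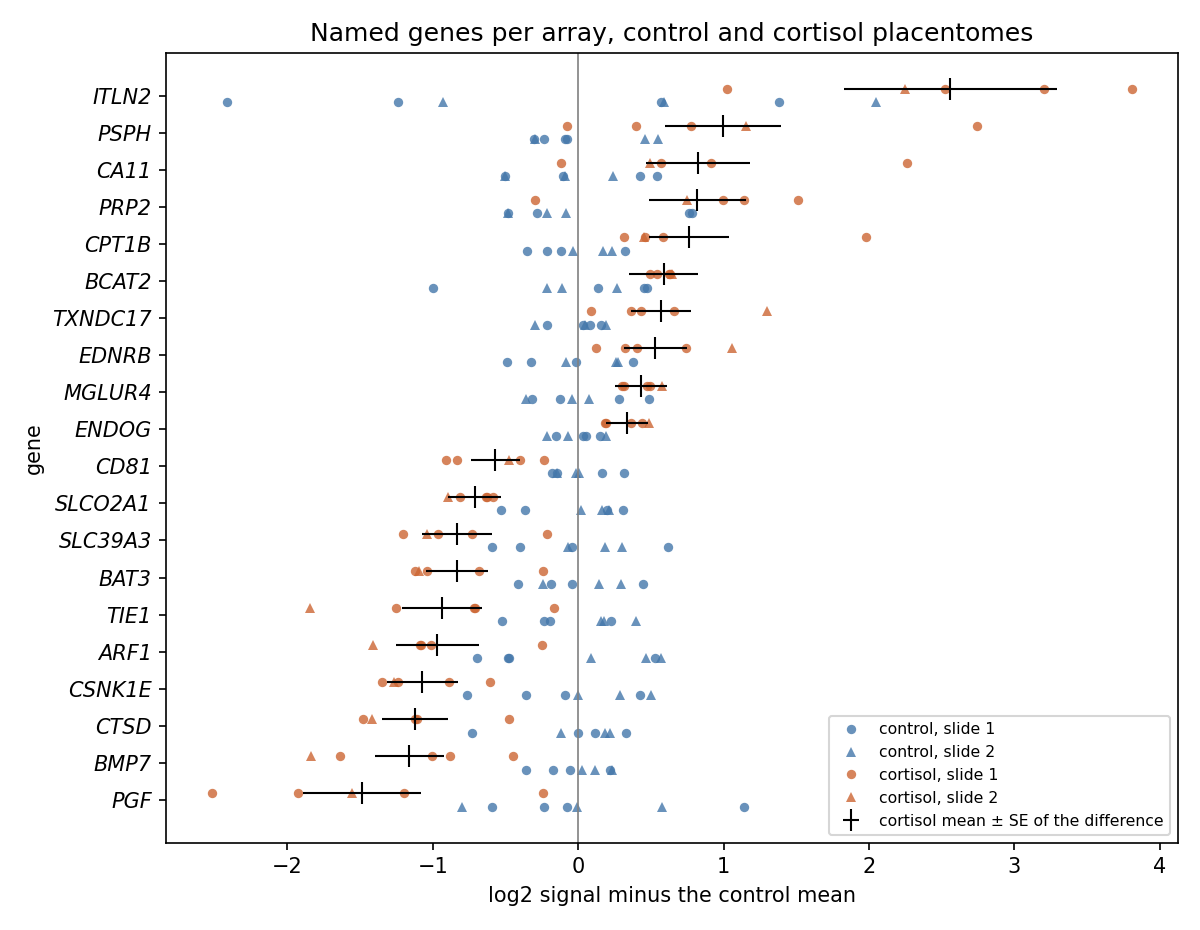
Each point is 1 array's log2 signal minus the control mean, with colour for the group. The genes are those with the smallest unadjusted p in each direction among probes with the same sign within both slides. PGF, BMP7 and CTSD lay below 0 on all 5 cortisol arrays and ITLN2 above 0 on all 5, with log2 fold changes of -1.49, -1.16, -1.12 and 2.56.

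Among genes that sense or convert cortisol, no difference passed the test. The glucocorticoid receptor gene NR3C1 had a log2 fold change of -0.32 ± 0.29 (SE; limma adjusted p = 0.992), with -0.01 within slide 1 and -0.91 within slide 2, and the mineralocorticoid receptor gene NR3C2 had -0.29 ± 0.32. HSD11B2, whose enzyme inactivates cortisol, had -0.27 ± 0.24, and HSD11B1, whose enzyme regenerates it, had 0.14 ± 0.38. PTGS2, the inducible enzyme of prostaglandin synthesis, had 0.05 ± 0.29 over 5 control and 5 cortisol values, and its other probe had -0.28. With slide as a block PTGS2 was at 0.32, with -0.0021 within slide 1 and 0.89 within slide 2, and HSD11B1 was at 0.26, with 0.52 and -0.44. With an array left out NR3C1 ranged from -0.51 to -0.17, NR3C2 from -0.52 to -0.13, HSD11B2 from -0.41 to -0.14, HSD11B1 from -0.06 to 0.31 and PTGS2 from -0.18 to 0.17. In the list of corticosteroid receptors and handling, 0 of 7 members passed, 2 were positive and 5 negative. The median was -0.29, with -0.01 within slide 1, -0.44 within slide 2 and -0.22 with slide as a block (camera adjusted p = 0.441), and cortisol 4 had a median deviation of 0.43, against -0.33 to -0.15 in the other cortisol arrays. Of the glucocorticoid-induced genes, 6 were measured, 2 positive and 4 negative, with CDKN1C, an inhibitor of cell division, at -0.50 ± 0.19 and IGFBP1, which binds insulin-like growth factors, at 1.03 ± 0.81. The other probes of IGFBP1 gave -0.27 and -0.06, and it was at 0.13 without cortisol 2 and 1.63 without cortisol 5. The named probe of IGFBP1 was well above background on only 4 of 7 control and 2 of 5 cortisol arrays. The median of that list was -0.04, with 0.24 within slide 1, -1.12 within slide 2 and -0.15 with slide as a block (camera adjusted p = 0.682), and it turned to 0.026 with normexp.

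Across the 26 lists tested, 0 passed an adjusted p of 0.05 with camera at the preset correlation, and 4 passed an unadjusted p of 0.05. With an estimated correlation 0 passed and 1 did unadjusted, and with fry 0 passed and 0 did unadjusted. The smallest adjusted p was 0.118, then 0.771 with an estimated correlation and 0.646 with fry. No member of a list passed over all probes. Adjusted over the list alone, PGF and TIE1 of angiogenesis and endothelium had a limma adjusted p of 0.0447 each, and no member of another list passed. This adjustment was repeated for each list with no correction across lists, so a pass in some list may arise by chance. Both genes were also among those named by smallest unadjusted p on these arrays. With an array left out PGF passed in this way in 4 of 12 fits (adjusted p = 0.00909 to 0.101) and TIE1 in 3 of 12 (adjusted p = 0.0201 to 0.136). With slide as a block neither passed (adjusted p = 0.0670 each), and with normexp TIE1 was at -0.17 (adjusted p = 0.655) and PGF at -1.52 (adjusted p = 0.0250). Of the 67 named probes, 20 changed sign under at least 1 alternative setting. The sign of the median differed from that of camera in 2 lists and from that of the mean in 4.

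The list of trophoblast products and keratins had the highest median of the 26, at 0.43 with 14 of 17 members positive (camera adjusted p = 0.118, adjusted p = 0.771 with an estimated correlation). Its members included pregnancy-associated glycoproteins, secreted by trophoblast, of which 8 of 8 were positive from 0.27 to 0.81, among them PAG7 at 0.65 ± 0.35 (0.42 to 1.01 with an array left out). The placental lactogen gene CSH1 had 0.18 ± 0.22 and TKDP1, a trophoblast Kunitz domain protein, 0.98 ± 0.61. The median was 0.16 within slide 1, 0.86 within slide 2 and 0.39 with slide as a block. In cortisol 2 the list's median deviation was -0.59, against 0.38 to 0.65 in the other cortisol arrays. Without cortisol 2 the list passed, with a median of 0.72 (camera adjusted p = 0.00108, adjusted p = 0.960 with an estimated correlation). It also passed without control 2, with a median of 0.57 (camera adjusted p = 0.0230, adjusted p = 0.704 with an estimated correlation), and without control 7, with 0.58 (camera adjusted p = 0.0247, adjusted p = 0.683 with an estimated correlation).

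Fatty acid uptake and oxidation had 8 of 8 members positive and a median of 0.31 (camera adjusted p = 0.118), with CPT1B at 0.76 ± 0.28 and the receptor gene PPARA at 0.72 ± 0.58. The median was 0.60 within slide 1, -0.19 within slide 2 and 0.31 with slide as a block. In cortisol 2 the list's median deviation was 1.64, against -0.45 to 0.17 in the other cortisol arrays, and PPARA was at -0.66, against -4.83 to -3.26. Without cortisol 2 the median of the list was 0.11 and PPARA was at 0.05, and without cortisol 5 PPARA was at 1.09. Branched-chain and serine-glycine metabolism had 4 of 6 positive and a median of 0.31 (camera adjusted p = 0.395), with PSPH at 1.00 ± 0.40 and MTHFD2 at 0.49 ± 0.29 (0.33 without cortisol 4). The median was 0.20 within slide 1, 0.23 within slide 2 and 0.24 with slide as a block, and in cortisol 2 its median deviation was 1.15, against -0.15 to 0.16 in the other cortisol arrays. Glucose transport and glycolysis had 10 of 13 negative and a median of -0.17 (camera adjusted p = 0.337), with the glycolytic enzyme genes PFKL at -0.59 ± 0.21 and ALDOA at -0.43 ± 0.18. The median was -0.13 within slide 1, 0.09 within slide 2 and -0.13 with slide as a block. Oxidative phosphorylation had 6 of 7 positive and a median of 0.13 (camera adjusted p = 0.445), with 0.23 within slide 1, 0.05 within slide 2 and 0.13 with slide as a block. Its members included ATP5MC1 at 0.15 ± 0.19 and COX5A at 0.42 ± 0.27, which turned to -0.07 with quantile normalization. With an array left out ATP5MC1 ranged from 0.03 to 0.26 and COX5A from 0.26 to 0.68. Cholesterol and lipid synthesis had 4 of 7 negative and a median of -0.10 (camera adjusted p = 0.741), with -0.14 within slide 1, -0.27 within slide 2 and -0.02 with slide as a block. LDLR, which takes up cholesterol, had -0.70 ± 0.40, or -0.18 with normexp and -0.43 without cortisol 5, and SCD, a fatty acid desaturase, 0.51 ± 0.28, or 0.29 without cortisol 1. Of lists too small to test, amino acid transport had a median of -0.46 over 4 genes, pyruvate dehydrogenase and TCA cycle -0.09 over 3, proteasome 0.14 over 4 and erythroid genes 0.43 over 3.

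Steroid and prostaglandin synthesis and labor had 11 of 15 members negative and a median of -0.23 (camera adjusted p = 0.118, adjusted p = 0.771 with an estimated correlation). The estrogen receptor gene ESR1 had -0.42 ± 0.18, the progesterone receptor gene PGR -0.47 ± 0.25 and CYP11A1, the first enzyme of steroid synthesis, -0.40 ± 0.23. The median was -0.09 within slide 1, -0.56 within slide 2 and -0.20 with slide as a block. Control 2 had a median deviation of -0.56, against -0.01 to 0.37 in the other controls, and without it the list passed with a median of -0.44 (camera adjusted p = 0.0230, adjusted p = 0.231 with an estimated correlation). The uterine gland and caruncular epithelium genes were chosen to mark maternal tissue, and whether they do so was not tested. They had 8 of 12 negative and a median of -0.18 (camera adjusted p = 0.598). Their median was 0.46 within slide 1, -1.53 within slide 2 and -0.25 with slide as a block. The IGF axis and growth list had 12 of 19 negative and a median of -0.14 (camera adjusted p = 0.282), with CDKN1C at -0.50 ± 0.19 and AKT1, a kinase of insulin signalling, at -0.53 ± 0.27. Without cortisol 5 AKT1 was at -0.32, and it was at -0.15 within slide 1 and -1.59 within slide 2. Its median was 0.14 within slide 1, -1.12 within slide 2 and -0.30 with slide as a block, and without cortisol 4 the list passed with -0.21 (camera adjusted p = 0.0397, adjusted p = 0.651 with an estimated correlation).

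Angiogenesis and endothelium had 11 of 19 members negative and a median of -0.09 (camera adjusted p = 0.525), with -0.14 within slide 1, -0.69 within slide 2 and -0.05 with slide as a block, and the median turned to 0.11 with normexp. Collagens and extracellular matrix had 11 of 16 negative and a median of -0.10 (camera adjusted p = 0.416), with BGN at -0.65 ± 0.24 and FBLN1 at -0.68 ± 0.31, both matrix proteins, and BGN was at -2.73 in control 2 against -1.91 to -1.45 in the other controls. The median was 0.18 within slide 1, -1.37 within slide 2 and -0.18 with slide as a block. Smooth muscle and fibroblast markers had 5 of 6 negative and a median of -0.24 (camera adjusted p = 0.395), with the contractile protein genes CNN1 at -0.53 ± 0.26 and TPM1 at -0.34 ± 0.28 (-0.53 to -0.16 with an array left out). The median was -0.40 within slide 2 and -0.25 with slide as a block, and near 0 within slide 1. Calcium, iron and ion transport had 8 of 14 positive and a median of 0.15 (camera adjusted p = 0.924), with 0.15 within slide 1, -0.50 within slide 2 and 0.13 with slide as a block, and it turned to -0.01 with the authors' values. The sodium channel genes SCNN1A and SCNN1B had -0.70 ± 0.26 and -0.94 ± 0.40, or -0.12 and -0.50 with normexp, and SCNN1B was at -3.88 in cortisol 5 against -2.25 to -1.81 in the other cortisol arrays. Without cortisol 5 the log2 fold change of SCNN1B was -0.56. Hypoxia response had 4 of 7 negative and a median of -0.07 (camera adjusted p = 0.525), with ARNT, a partner of the hypoxia-inducible factors, at -0.28 ± 0.24, or -0.05 without cortisol 5. The median was -0.12 within slide 1, -0.02 within slide 2 and -0.06 with slide as a block.

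Among immune lists, inflammation and cytokine signalling had 15 of 24 members positive and a median of 0.07 (camera adjusted p = 0.635). IL1A, a cytokine, was at 0.85 ± 0.47 (0.43 without cortisol 2) and its receptor antagonist IL1RN at -0.52 ± 0.21. IL1A was well above background on only 5 of 7 control and 3 of 5 cortisol arrays. The median was 0.33 within slide 1, -0.51 within slide 2 and 0.08 with slide as a block, and it turned to -0.06 with quantile normalization and was also negative with median centring, the authors' values, and normexp then quantile normalization. Lymphocyte and NK markers had 6 of 7 positive and a median of 0.20 (camera adjusted p = 0.525), with 0.50 within slide 1, -0.90 within slide 2 and 0.23 with slide as a block. Their T cell receptor gene CD3D had 0.55 ± 0.38, or 0.89 without cortisol 5, and CD247 was not well above background on any cortisol array. Myeloid and granulocyte markers had 8 of 12 positive and a median of 0.13 (camera adjusted p = 0.635), with FCGR1A, a receptor for antibodies, at 0.16 ± 0.24 (0.04 to 0.30 with an array left out) and the antimicrobial peptide gene SC5 at 0.49 ± 0.27. The median was 0.20 within slide 1, -0.16 within slide 2 and 0.07 with slide as a block, and it turned to -0.10 with quantile normalization and was also negative with the authors' values and with normexp then quantile normalization. Antigen presentation had 4 of 5 negative and a median of -0.16 (camera adjusted p = 0.525), with LGMN at -0.24 ± 0.23 and OVAR-DQA1 at -0.34 ± 0.37, whose other probe had 0.58. LGMN was at -0.16 with slide as a block, and with an array left out it ranged from -0.41 to -0.12 and OVAR-DQA1 from -0.60 to -0.06. The median was -0.01 within slide 1, -0.15 within slide 2 and -0.16 with slide as a block. Interferon response had 5 of 9 negative and a median of -0.10 (camera adjusted p = 0.611), with the interferon regulatory factors IRF3 at -0.33 ± 0.14 and IRF2 at 0.32 ± 0.21 (0.21 to 0.49 with an array left out). The median was 0.12 within slide 1, -0.74 within slide 2 and -0.25 with slide as a block, and control 2 had a median deviation of -0.48, against 0.01 to 0.25 in the other controls.

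Ribosomal proteins had 15 of 19 members positive and a median of 0.12 (camera adjusted p = 0.413), with RPS12 at 0.35 ± 0.16 and RPSA at -0.37 ± 0.22, and the median turned to -0.02 with median centring. It was 0.11 within slide 1, 0.17 within slide 2 and 0.13 with slide as a block. In cortisol 2 its median deviation was -0.41, against 0.12 to 0.30 in the other cortisol arrays, and without cortisol 2 the list passed with a median of 0.25 (camera adjusted p = 0.00108, adjusted p = 0.960 with an estimated correlation). Cell cycle had 5 of 10 positive and a median of 0.07 (camera adjusted p = 0.611), with ASPM, a spindle protein, at 0.63 ± 0.31 and the kinase gene CDK1 at 0.37 ± 0.35 (0.19 to 0.63 with an array left out). The median was 0.03 within slide 1, 0.13 within slide 2 and 0.04 with slide as a block, and it turned to -0.04 with median centring and was also just below 0 with the authors' values and with normexp then quantile normalization. ASPM was at -2.39 in cortisol 2, against -4.16 to -3.67 in the other cortisol arrays, and without cortisol 2 it had 0.33. Apoptosis and p53 had 6 of 10 positive and a median of 0.17 (camera adjusted p = 0.413), with the death receptor gene FAS at 0.55 ± 0.37 (0.27 without cortisol 2). The median was 0.29 within slide 1, -0.44 within slide 2 and 0.13 with slide as a block. Unfolded protein and heat shock response had 5 of 8 negative and a median of -0.14 (camera adjusted p = 0.777). CRYAB, a small heat shock protein, was at 0.74 ± 0.35 and the stress factor gene DDIT3 at 0.83 ± 0.42 (0.43 without cortisol 2). DDIT3 was well above background on only 4 of 7 control and 4 of 5 cortisol arrays. The median was 0.25 within slide 1, -0.87 within slide 2 and -0.20 with slide as a block. Antioxidant defence had 3 of 6 positive and a median of -0.01 (camera adjusted p = 0.741), with GSTM3 at 0.51 ± 0.36 (0.23 without cortisol 4) and GLRX at 0.40 ± 0.48. GLRX was at 0.63 with slide as a block and ranged from -0.17 to 0.67 with an array left out. The median was 0.06 within slide 1, 0.32 within slide 2 and 0.05 with slide as a block, and it turned to 0.025 with quantile normalization and was also positive with normexp, the authors' values, and normexp then quantile normalization.

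**Figure D3:**
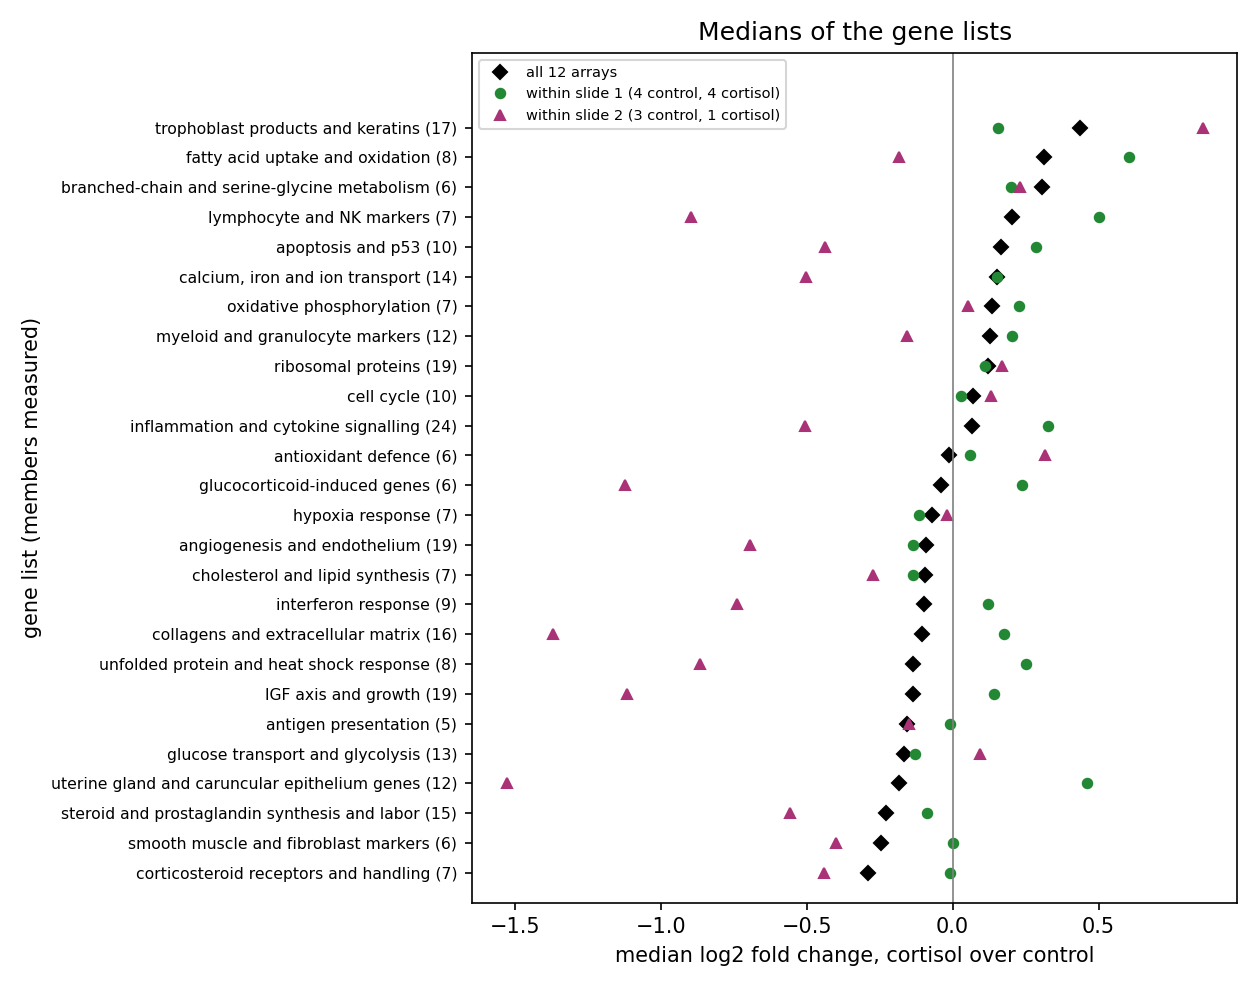
The median log2 fold change of cortisol over control is plotted for the 26 lists tested, over all 12 arrays (diamonds), within slide 1 (circles) and within slide 2 (triangles), with the number of measured members in brackets. The medians over all arrays run from -0.29 to 0.43, and that of uterine gland and caruncular epithelium genes is 0.46 within slide 1 and -1.53 within slide 2.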

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

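The tests of cortisol 5, of the scaling, of the GC content, of the array of cortisol 2 and its trophoblast share, of the trophoblast families and of the PAG probes, and the splits within slides and under other scalings, were chosen after the results they explain, or values they use, had been seen, and the other counts over 100 splits of the arrays were set out before. Of 202 groups of values tested for a lone sample far from the others, 15 had one, where chance gives about 1 in 20. Cortisol 2 was that sample in 8 of them.

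The first pattern was the array of cortisol 2, whose negative controls had a mean of 92.6, against 38.4 to 42.5 in the other cortisol samples, and whose spike-in r2 was 0.958, against 0.985 to 0.988. Negative controls and spike-ins do not measure the tissue, so another share of trophoblast would not give those values. The deviation of this array from the others was correlated across probes with their mean level (r = -0.665, against -0.128 to 0.339 on the others). Probes are not independent replicates. A raised background or compressed labelling would give such a correlation, and these may be the cause. The sign of r means that dim probes lay high on this array. PSPH, CA11, CPT1B, PPARA and ASPM had mean log2 values of -3.97 to -2.16 and were higher here than on the other cortisol arrays. The array may thus account for part of their higher values with cortisol. Once the mean level of its members was taken into account, its trophoblast list was at -0.21, below the other cortisol arrays (0.19 to 0.59) and within the controls (-0.75 to 0.41), so another share of trophoblast in this sample also stays open.

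The second pattern was the excess of lower over higher probes, 80.9% of the 618 past an unadjusted p of 0.05. Splits of the 12 arrays, 100 in all with the real one among them, were drawn from 792 possible. Of these, 3 had a share as high, counting the real one, with 82.7% as the highest other. The groups lie unevenly on the slides, and 280 splits keep the slides. All 280 were run first, and 12 had a share as high. Of 100 drawn from them 6 were as high (highest other 86.3%). Both proportions lie near 0.05, on either side of it, so chance was not excluded. Within slide 1 the share was 38.8% of 482. The share was 66.7% with normexp, a change of background correction, reached by 67 of 100 splits. It was 72.3% with median centring, a change of scaling, reached by 26. It was 80.6% with quantile normalization and 84.4% with the authors' values, reached by 1 each, and 82.3% with normexp then quantile normalization. The background correction or the scaling may therefore account for part of the excess, though not every change lowered it. Without cortisol 5 the lower probes numbered 511, with 335 of the 500 kept. The 500 were picked on these same arrays, and with any array left out 335 to 443 of them were kept. The number kept therefore cannot decide whether cortisol 5 caused the lower probes. Without it the higher probes numbered 685 rather than 118, so the array may account for how few were higher (share lower 42.7%). In the third of the probes with the lowest GC content the share was 57.0% of 79 probes, against 82.6% of 241 and 85.9% of 298 in the others, with r = -0.0137 between GC content and log2 fold change over all tested probes, so a GC bias among these probes cannot be told apart from an effect on GC-rich genes, and an effect of cortisol stays open.

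The third pattern was the positive median of the trophoblast list, 0.43. As large a median came from 23 of 100 splits, counting the real one, with 0.96 as the highest other, so chance was not excluded. The 13 members of the PAG, PRP and TKDP families had a median of 0.65 and the other 4 had 0.04, and the families' deviation minus that of the others was larger with cortisol by 0.60 over all arrays (exact permutation p = 0.0404, two-sided), by 0.31 within slide 1, by 1.13 within slide 2 with its lone cortisol array, and by 0.54 with slide as a block (permuted within slides, p = 0.0679). The families were set by gene name and not by trophoblast cell type. A larger share of all trophoblast and a change among trophoblast cell types therefore both stay open. The deviations of the 8 PAG probes from their group means had a mean correlation of 0.590, so probes that bind each other's transcripts may add to the agreement of the family, and shared regulation would give the same.

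As many as the 618 probes past unadjusted p (577 with a trended and robust prior) came from 28 of 100 splits, counting the real one, so chance was not excluded for this count, and the highest other, 2326, points to a structure of the samples beyond the groups. For the 0 probes past the adjusted threshold with limma, and the 0 lists with camera (4 unadjusted, 0 with an estimated correlation or fry), all 100 of 100 splits have at least as many whatever the data, so these 2 comparisons decide nothing about chance. The highest counts in the other splits were 79 probes and 7 lists, and 64 of the other splits called at least 1 list.

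The 75th percentile of cortisol 5 was 791, against 251 to 369 in the other cortisol arrays. In cortisol 2 the log2 value of ASPM was -2.39 (others -4.16 to -3.67), that of RPS12 8.10 (others 8.56 to 8.73) and that of CPT1B -0.50 (others -2.16 to -1.89). SCNN1B was at -3.88 in cortisol 5 (others -2.25 to -1.81). In control 2 CTSD was at 3.46 (others 4.07 to 4.52) and BGN at -2.73 (others -1.91 to -1.45). Median deviations of lists stood apart in cortisol 2 for trophoblast products and keratins at -0.59, branched-chain and serine-glycine metabolism at 1.15 and ribosomal proteins at -0.41. They did so in control 2 for steroid and prostaglandin synthesis and labor at -0.56 and interferon response at -0.48, and in cortisol 4 for corticosteroid receptors and handling at 0.43.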

How the results depend on the processing

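The fits without both cortisol 2 and cortisol 5, of replicates 1 to 5 without a block, and with normexp followed by quantile normalization were chosen after the results had been seen. Over 30 alternatives, 47 of 67 named probes kept their sign and 20 changed it under at least 1, with 38 of 2000 values reversed. Outside the fit within slide 2, 0 of these values passed the adjusted threshold. The 20 genes of the first part were chosen for the same sign within both slides, and the slides are among the alternatives. List members were mostly named by smallest unadjusted p on these same arrays. Both choices favour a kept sign. Among list medians, 7 of 26 kept their sign under all alternatives and 19 did not, and 17 of 780 values moved by more than the spread between arrays. Each of the 26 medians was smaller than its own spread. A median could therefore vanish or turn without counting as moved, and the 17 do not show that the others were stable. Set tests were not run with slide as a random block. Signal over background limits dim genes: 8 probes were not well above background on any cortisol array. The cause was not tested for any difference below.

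The probes past adjusted p numbered 1 with quantile normalization, the authors' values, normexp then quantile normalization, and array weights, the unnamed probe A_70_P063496 (-2.93, -2.06, -1.08 and -3.04), singled out after its values were seen. Within slide 2 they numbered 3564, 759 higher and 2805 lower, and with an array left out 0 to 1 (A_70_P059876, -1.56, without cortisol 4), with 0 to 0 higher and 0 to 1 lower. The probes past unadjusted p numbered 5393 (1584 higher, 3809 lower) within slide 2, 2017 (758, 1259) with array weights, 1423 (596, 827) without cortisol 2 and cortisol 5, and 482 (295, 187) within slide 1. The higher probes numbered 248 with no filter and 73 for replicates 1 to 5 without a block, and the lower ones 316 with normexp, 758 with the authors' values and 755 with normexp then quantile normalization. With an array left out they numbered 446 to 1198, 72 to 685 higher and 357 to 985 lower. The share of lower probes was 66.7% with normexp, 72.3% with median centring and 80.9% as reported, and the median of all probes shifted by -0.10 with quantile normalization and by -0.11 with median centring.

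The replicate block gave 0 probes past adjusted p and 271 unadjusted, 79 higher and 192 lower, against 413 for the same arrays without it. Samples with the same number had correlations of -0.27 to 0.05, with 0 of 5 pairs over 0.1 and 0 best with their own number. No tie between equal numbers was thus seen in the values. The pairs numbered 1, 2, 3 and 5 did share a slide, and 5 pairs cannot show that nothing else was shared.

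Lists past adjusted p numbered 2 with quantile normalization and with the authors' values (trophoblast, fatty acid), and 1 with median centring (fatty acid), within slide 2, with array weights, with probes of a symbol averaged and without cortisol 2 and cortisol 5 (all trophoblast), and 0 to 2 with an array left out. With an estimated correlation the adjusted p of all lists called was 0.216 to 0.977. With fry it was 0.0177 for fatty acid with median centring, which passed, and 0.0752 to 0.743 for the others, and fry gave none with array weights.

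Reversed log2 fold changes within slide 2 were PPARA -1.01, CNN1 0.0048, FCGR1A -0.23, LGMN 0.32, COX5A -0.66, CD3D -0.95, SCD -0.15, DDIT3 -0.45, RPSA 0.035, HSD11B2 0.20, HSD11B1 -0.44 and IGFBP1 -1.49, and within slide 1 ARNT 0.037, PTGS2 -0.0021, CDK1 -0.019, OVAR-DQA1 0.089 and GLRX -0.10. They were FCGR1A -0.023, COX5A -0.073 and EDNRB -0.0090 with quantile normalization, FCGR1A -0.051 with the authors' values, FCGR1A -0.0021 and PTGS2 -0.0099 with normexp then quantile normalization, and PTGS2 -0.028 with normexp. CD247 was fitted at 0.10 with normexp, but no sign is read for it, since it was not well above background on any cortisol array. PTGS2 was -0.0062 for replicates 1 to 5 without a block, PTGS2 -0.12 and NR3C2 0.12 with array weights, PTGS2 -0.11, CDK1 -0.063 and GLRX -0.17 without cortisol 2 and cortisol 5, and OVAR-DQA1 0.12 with probes averaged. With an array left out PTGS2 ranged from -0.18 to 0.17, HSD11B1 from -0.064 to 0.31 and GLRX from -0.17 to 0.67.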

Other observations

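The medians of the trophoblast list and of the uterine gland and caruncular epithelium list were compared across the 12 arrays. This relation was chosen after the results had been seen. The lists were meant to mark the fetal and the maternal side, and whether they do so was not tested. Pearson's r was -0.476 (permutation p = 0.115) and Spearman's rho -0.476 (permutation p = 0.122), and r was -0.322 without control 6 and cortisol 2. The relation did not pass a threshold of 0.05, and was the only one of its kind computed.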
